A study of Homo sapiens with 9 samples.

How the data were processed

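RNA was measured by poly(A)-selected, strand-specific sequencing (TruSeq stranded mRNA kit, per the labels' protocols) in 9 cultures of MDA-MB-231, a triple-negative human breast cancer line. The cells had been transduced with a lentiviral vector that was empty, carried wild-type MEL-18 or carried MEL-18 T334A, in which threonine is replaced by alanine at a residue described as a phosphorylation site. Each group held 3 libraries that the series describes as biological replicates. Neither the labels nor the design text says whether the replicates came from separate transductions, so the p-values measure the spread between these cultures, and a difference between constructs cannot be separated from a difference between the transduced lines.

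The deposited files hold whole-number read counts per gene symbol, with no normalization, made by the authors with CASAVA 1.8, STAR 2.5.3a and featureCounts from Subread 1.5.3 on the hg19 genome, per the submitters' processing notes. The gene annotation, the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. Counts of antisense genes, of genes that overlap others and of near-identical family members are therefore uncertain. The files held 26364 genes and no blank or total rows. Library totals ran from 31643722 to 37005302 counts.

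Genes with enough counts by edgeR's filterByExpr (14738 of 26364) were tested, and they held 99.9% or more of the counts of each library. Libraries were scaled by TMM, with factors from 0.979 to 1.02. The main test was edgeR's quasi-likelihood F test, two-sided, on all 9 libraries with a mean per group and no replicate term, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The common dispersion corresponded to a biological coefficient of variation of 2.57%. Values in the text are CPM as edgeR computes them over the TMM-scaled library sizes, given as mean ± SD with n = 3 libraries per group, and log2 fold changes ± SE, where the SE is the absolute log2 fold change over the square root of F. For named genes with few counts, the ratio of summed counts is given with its exact 95% binomial interval, which covers counting error alone.

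The comparisons, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. The rule named PCGF2 and BMI1. For each comparison it then took, among called genes with a mean of at least 2 CPM over the 9 libraries and no overlap between the replicates of the groups, the 12 with the most positive and the 12 with the most negative log2 fold change, leaving out uncharacterised, antisense and small RNA names. From each list it took up to 4 called members with the largest absolute change. The text gives part of the genes that the rule took, chosen after their values were seen, and one gene that it took from a list is not reported here. Lists with at least 5 tested members (29 of 30) were tested with limma's camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists. PCGF2 was left out of the lists, since it was overexpressed.

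Replicates were compared by a chi-square test of their counts. The 9 pairs within groups had chi-square values of 1.49 to 3.98 per degree of freedom, so that each of these pairs differed by more than sampling noise. The highest values, 3.64 and 3.98, were those of MEL-18 T334A replicate 3 against replicates 1 and 2, and the next was 2.77. Pairs across groups were not compared in this way. The fits were tested on simulated counts for the real genes with known changes. In the simulation of MEL-18 WT against the vector, 53.8% of genes changed 1.2-fold, 88.8% of those changed 1.5-fold and 95% of those changed 2-fold were recovered, with 5 false calls among 157. For MEL-18 T334A against the vector the recovered shares were 58.8%, 75% and 95%, with 9 false calls among 154, and for MEL-18 T334A against MEL-18 WT they were 72.5%, 77.5% and 97.5%, with 10 among 169. In a simulated list test, the raised list was found and 0 of 28 other lists were called.

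The overlap of both comparisons with the shared vector libraries was set against 100 simulated datasets of unchanged groups and against independent lists. Alternatives were DESeq2 with its own size factors, RLE factors, library totals alone, no filter, a filter of at least 1 CPM in at least 3 libraries, a term for the replicate number, a fit of the compared groups alone, a test against a minimum change of 1.5-fold, limma voom, counts thinned to the smallest library, and the removal of each library in turn. An alternative chosen after the data were seen took out the shift of chromosomal neighbours. The median deviation of the 20 expressed genes on each side of a gene entered the fit as an offset per group. The offset came from the same libraries and was taken as known, so p-values after this step leave out its error. In simulated data, 66 of 100 genes in a shifted stretch were called before and 0 after this step. In the real data the step lowered the correlation of adjacent genes but did not remove it. The order of genes came from NCBI's GRCh38.p14 gene table, which placed 14423 of the 14738 tested genes by symbol or synonym (97.9%). It served for names and neighbours alone, since the counts were made on hg19, and no coordinates are given. GC content and length were those of the longest GENCODE transcript of 14294 genes (97.0%). Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.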

Results

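The transcriptomes of MDA-MB-231 cells that stably carried an empty lentiviral vector, wild-type MEL-18 (MEL-18 WT) or the phosphorylation-deficient mutant MEL-18 T334A were compared, with 3 libraries in each of 3 groups. MEL-18, encoded by PCGF2, is a Polycomb group RING finger protein of the repressive complex PRC1 and a paralog of BMI1. The libraries held 31643722 to 37005302 counts over 26364 genes, of which 14738 were tested. The first principal component took 43.1% of the variance and the second 29.03%. Between 18956 and 19636 genes had at least 1 count in 8 of the libraries, and 20323 in MEL-18 T334A replicate 1.

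PCGF2 was raised in every library that was labelled as carrying MEL-18. It stood at 22.7 ± 0.88 CPM (SD, n = 3) with the empty vector, at 1286 ± 6.55 CPM with MEL-18 WT and at 1420 ± 30.9 CPM with MEL-18 T334A, 56.5-fold and 62.4-fold above the vector. MEL-18 T334A cells held more PCGF2 RNA than MEL-18 WT cells, by 0.14 ± 0.03 on the log2 scale (edgeR quasi-likelihood test, adjusted p = 1.48e-04). Reads of the transgene and of the endogenous gene were not told apart. BMI1 was low in all groups, at 4.02 ± 0.55, 3.61 ± 0.22 and 3.61 ± 0.33 CPM with the vector, MEL-18 WT and MEL-18 T334A, and was not called in any of the 3 comparisons.

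**Figure D1:**
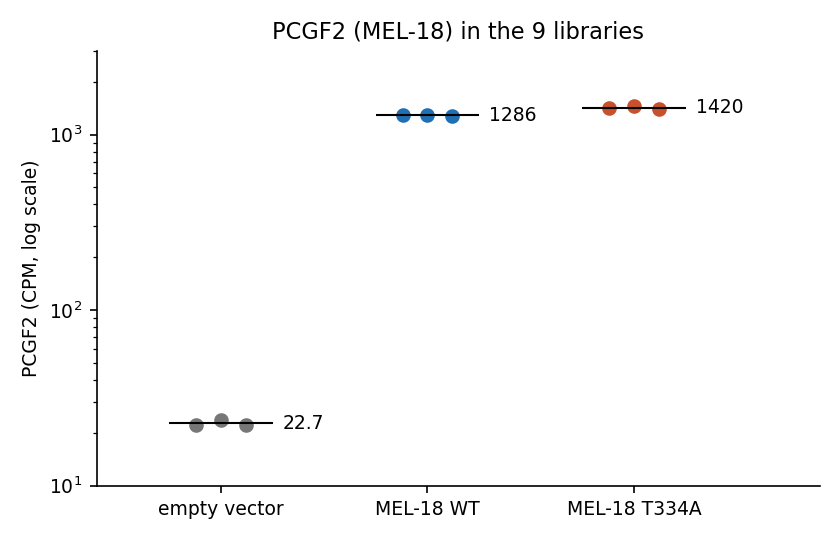
PCGF2 in CPM (vertical axis, log scale) in each of the 9 libraries (points) by group (horizontal axis), with the group mean as a line and a number. The vector libraries lie near 22.7 CPM and the MEL-18 libraries between 1279 and 1451 CPM.

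The comparison of MEL-18 WT with the vector asked which transcripts changed with wild-type MEL-18. Among the genes named by the rule, the largest increase was in LY9, a SLAM family receptor of lymphocytes, with 1115 counts over the 3 MEL-18 WT libraries against 5 with the vector, a ratio of 206 (exact 95% interval 88.0 to 636). TMPRSS15, the intestinal protease enteropeptidase, rose from 2.51 ± 0.25 to 82.7 ± 1.84 CPM (log2 fold change 5.04 ± 0.06). ITM2A rose by 4.23 ± 0.18, GLB1L2 by 3.79 ± 0.18, RASGRP3, a Ras guanine nucleotide exchange factor, by 2.75 ± 0.10 and PDGFRA, the PDGF receptor alpha, by 2.08 ± 0.08 on the log2 scale. CNTNAP2 rose by 2.12 ± 0.19 and ANKS1B by 2.22 ± 0.17. FABP4, a fatty acid binding protein, fell by 2.42 ± 0.20, from 2.96 ± 0.09 to 0.55 ± 0.16 CPM. SUSD2 fell from 43.5 ± 1.14 to 8.90 ± 0.91 CPM, and S100A4, a calcium-binding protein linked to metastasis, from 24.0 ± 1.37 to 8.21 ± 0.81 CPM, where the neighbours of S100A4 on chromosome 1 had a median log2 fold change of -0.20. The cystatins CST1 and CST4 fell by 1.29 ± 0.08 and 1.21 ± 0.12, with the caution that they are close family members, and F13A1, KRT81 and the AP-1 gene FOSB fell by 1.03 ± 0.08, 1.12 ± 0.11 and 0.99 ± 0.17. The neighbours of LY9, RASGRP3 and CNTNAP2 had medians of -0.21, -0.12 and -0.11.

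In all, 4242 genes were called between MEL-18 WT and the vector, 2124 higher and 2118 lower, with a median change of 1.16-fold. Of these, 260 changed more than 2-fold, 197 of them higher and 63 lower. The replicates of the groups did not overlap in 42.7% of tested genes, against 10% by chance. Against a minimum change of 1.5-fold the count was 191. With library totals in place of TMM, 60.1% of calls were higher, against 50.1% with TMM.

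Among the lists, HOX genes, Wnt pathway targets and breast cancer stem cell markers stood higher with MEL-18 WT, and sterol synthesis, immediate early and G2/M genes lower, at the preset correlation. Of 15 HOX genes tested, 5 rose and 0 fell (5 rose adjusted over the list alone; camera adjusted p = 0.00713, and adjusted p = 0.169 with an estimated correlation), among them HOXB8 (log2 fold change 1.21 ± 0.24), HOXB9 (0.83 ± 0.06) and HOXC10 (0.63 ± 0.12). Of 19 Wnt targets, 12 rose and 0 fell (13 and 1 adjusted over the list alone; adjusted p = 6.37e-04, and adjusted p = 0.127 with an estimated correlation). They included LGR5, a receptor of R-spondins, at 1.59 ± 0.34, the Wnt inhibitor NKD1 at 1.01 ± 0.26, and NOTUM, which also restrains Wnt signalling, with 38 counts against 6 over 3 libraries each (ratio 5.85, 95% interval 2.45 to 16.9). In the stem cell list 10 of 15 rose and 2 fell (10 and 3 adjusted over the list alone; adjusted p = 0.0285, and adjusted p = 0.459 with an estimated correlation), with the transporter ABCG2 at 0.83 ± 0.11 and the aldehyde dehydrogenase ALDH1A3 at 0.59 ± 0.08. The Wnt and stem cell lists were both set to hold CD44, LGR5 and MYC, so their calls are not independent. The stem cell list also held CD24 and EPCAM, which stood in the epithelial list as well. A rise of its members is therefore not by itself a rise of a stem cell state. Sterol and fatty acid synthesis genes fell in 19 of 32 cases and rose in 1 (23 and 1 adjusted over the list alone; adjusted p = 2.82e-07, and adjusted p = 0.180 with an estimated correlation). Squalene synthase, FDFT1, fell from 298 ± 2.37 to 224 ± 4.99 CPM (-0.41 ± 0.03), while its neighbours on chromosome 8 had a median of -0.23. HSD17B7, on chromosome 1, fell by 0.45 ± 0.05 beside neighbours at -0.21. In the immediate early list 14 of 25 fell and 3 rose (16 and 3 adjusted over the list alone; adjusted p = 0.00713, and adjusted p = 0.278 with an estimated correlation), with DUSP1 at -0.60 ± 0.04 and FOSL2 at -0.46 ± 0.04, the latter beside neighbours at -0.12. G2/M genes fell in 13 of 34 cases and rose in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.00976, adjusted p = 0.724 with an estimated correlation, and adjusted p = 0.0530 without MEL-18 WT replicate 1); NUF2 was lowest at -0.38 ± 0.03, beside chromosome 1 neighbours at -0.20. The other 23 lists tested were not called. They included PRC1 subunits, with 7 of 23 higher and 2 lower, mesenchymal markers, with 12 of 28 higher and 5 lower, epithelial markers, with 7 of 24 higher and 4 lower, and interferon-stimulated genes, with 9 of 39 higher and 10 lower. Adjusted over the list alone, these numbers were 8 and 3, 12 and 6, 8 and 4, and 10 and 10.

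MEL-18 T334A against the vector addressed the effect of the mutant protein. RYR2, the calcium release channel of heart muscle, rose from 0.34 ± 0.09 to 17.2 ± 0.999 CPM (log2 fold change 5.65 ± 0.14), and EPHA5, an ephrin receptor of the nervous system, from 0.68 ± 0.06 to 20.1 ± 1.61 CPM (4.88 ± 0.11). CNTNAP2 rose by 3.04 ± 0.17, the potassium channel KCNN3 by 2.80 ± 0.14, the septin SEPT3 by 2.56 ± 0.09 and GPM6A by 2.41 ± 0.11. C2CD4C, GLB1L2, DUSP9 and ITM2A, raised in MEL-18 WT cells, were raised here by 2.99 ± 0.16, 2.68 ± 0.21, 2.66 ± 0.14 and 2.45 ± 0.24. The cancer-testis gene MAGEB1 fell from 4.64 ± 0.30 to 0.14 ± 0.03 CPM (-5.06 ± 0.21), RPE65 by 3.11 ± 0.18, the myosin MYH13 by 3.06 ± 0.21 and the phosphatase CPPED1 by 2.93 ± 0.12. PDGFRA fell by 2.46 ± 0.16, FOSB by 2.75 ± 0.22, the collagen COL4A5 by 1.95 ± 0.10, S100A4 by 1.73 ± 0.08 and SUSD2 by 1.58 ± 0.06. The neighbours of S100A4, MAGEB1, GPM6A, RYR2 and SEPT3 had medians of -0.12, -0.13, -0.19, 0.13 and 0.11.

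The count was 6765 genes, 3455 higher and 3310 lower, with a median change of 1.16-fold. More than 2-fold changes were seen in 399, 273 higher and 126 lower. Replicates did not overlap in 51.5% of tested genes. Against a minimum of 1.5-fold, 378 genes were called, and with library totals alone 64.0% of calls were higher, against 51.1% with TMM.

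Lists called against the vector in MEL-18 T334A cells numbered 11 at the preset correlation, 0 with an estimated correlation, and, at the preset one, 7 without empty vector replicate 1 or without MEL-18 T334A replicate 1. HOX genes rose in 5 of 15 cases, with 0 lower, Wnt targets in 11 of 19, with 0 lower, and stem cell markers in 9 of 15, with 1 lower, the same numbers adjusted over the list alone. Their adjusted p was 0.0190, 0.00900 and 0.00900, and with an estimated correlation adjusted p = 0.379, 0.299 and 0.379. LGR5 rose by 1.94 ± 0.32, TCF7, a Wnt-linked transcription factor, by 0.86 ± 0.11, ITGB3 by 0.73 ± 0.09 and HOXB9 by 0.56 ± 0.06. Other developmental transcription factors rose in 15 of 32 cases and fell in 1 (the same adjusted over the list alone; adjusted p = 0.0111, and adjusted p = 0.379 with an estimated correlation), with PRRX1 at 1.66 ± 0.16 and LHX6 at 1.37 ± 0.14. Notch pathway genes rose in 8 of 17 cases and fell in 1 (the same adjusted over the list alone; adjusted p = 0.0213, and adjusted p = 0.379 with an estimated correlation), with HES4 at 1.06 ± 0.11, the ligand JAG2 at 0.88 ± 0.11 and the receptor NOTCH3 at -0.77 ± 0.15. Collagens and laminins rose in 15 of 31 cases and fell in 5 (the same adjusted over the list alone; adjusted p = 0.0190, and adjusted p = 0.649 with an estimated correlation), with LAMA3 at 1.12 ± 0.15 beside neighbours at 0.19. Among those that fell, COL4A5, given above, and COL4A6, with 12 counts against 62 (ratio 5.44), changed by more than LAMA3. The median log2 fold change of the list was 0.14 and its mean 0.06.

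Lower lists were those of heat shock, immediate early, G2/M, S phase and ribosomal protein genes. Heat shock genes fell in 11 of 16 cases and rose in 2, also adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.382 with an estimated correlation); the chaperone HSP90AA1 fell by 0.40 ± 0.04 and HSPH1 by 0.35 ± 0.03. Immediate early genes fell in 13 of 25 cases and rose in 3 (13 and 4 adjusted over the list alone; adjusted p = 0.0190, and adjusted p = 0.379 with an estimated correlation), with DUSP1 at -1.01 ± 0.04 and FOS at -0.95 ± 0.05. G2/M genes fell in 21 of 34 cases and rose in 4 (23 and 5 adjusted over the list alone; adjusted p = 0.00900, and adjusted p = 0.708 with an estimated correlation). ECT2 fell by 0.45 ± 0.03 beside chromosome 3 neighbours at -0.24, while the proliferation marker MKI67 rose by 0.25 ± 0.03 beside chromosome 10 neighbours at 0.36. With the neighbours' shift taken out, an alternative chosen after the data were seen, MKI67 was called lower (-0.119, edgeR adjusted p = 0.00326). That p-value takes the shift as known and leaves out its error, so the change of sign is uncertain. S phase genes fell in 17 of 37 cases and rose in 5 (20 and 6 adjusted over the list alone; adjusted p = 0.0190, and adjusted p = 0.746 with an estimated correlation), with RRM2 at -0.29 ± 0.04. Ribosomal protein genes fell in 24 of 52 cases and rose in 4 (25 and 5 adjusted over the list alone; adjusted p = 0.0190, and adjusted p = 0.746 with an estimated correlation), with RPL24 at -0.28 ± 0.03 beside chromosome 3 neighbours at -0.17. Of the nuclear-retained RNAs, which were too few for the list test, MALAT1 fell by 0.41 ± 0.04. NEAT1 fell by 0.12 ± 0.04 (adjusted p = 0.0143), a call that was lost with DESeq2 (adjusted p = 0.105), with library totals alone (0.112), without empty vector replicate 3 (0.120) and without MEL-18 T334A replicate 3 (0.0893). Without empty vector replicate 1 the calls of the Notch (adjusted p = 0.0572), S phase (0.0572), collagen (0.0595) and ribosomal (0.160) lists were lost, and without MEL-18 T334A replicate 1 the same 4 were lost (0.0515, 0.0556, 0.0556 and 0.165). Without MEL-18 T334A replicate 2 the Notch (0.0677) and S phase (0.0727) calls were lost. With library totals alone the Notch, collagen and ribosomal calls were lost (adjusted p = 0.0513 for each), and with the shift of the neighbours taken out those of the S phase and collagen lists (0.0793 for each).

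**Figure D2:**
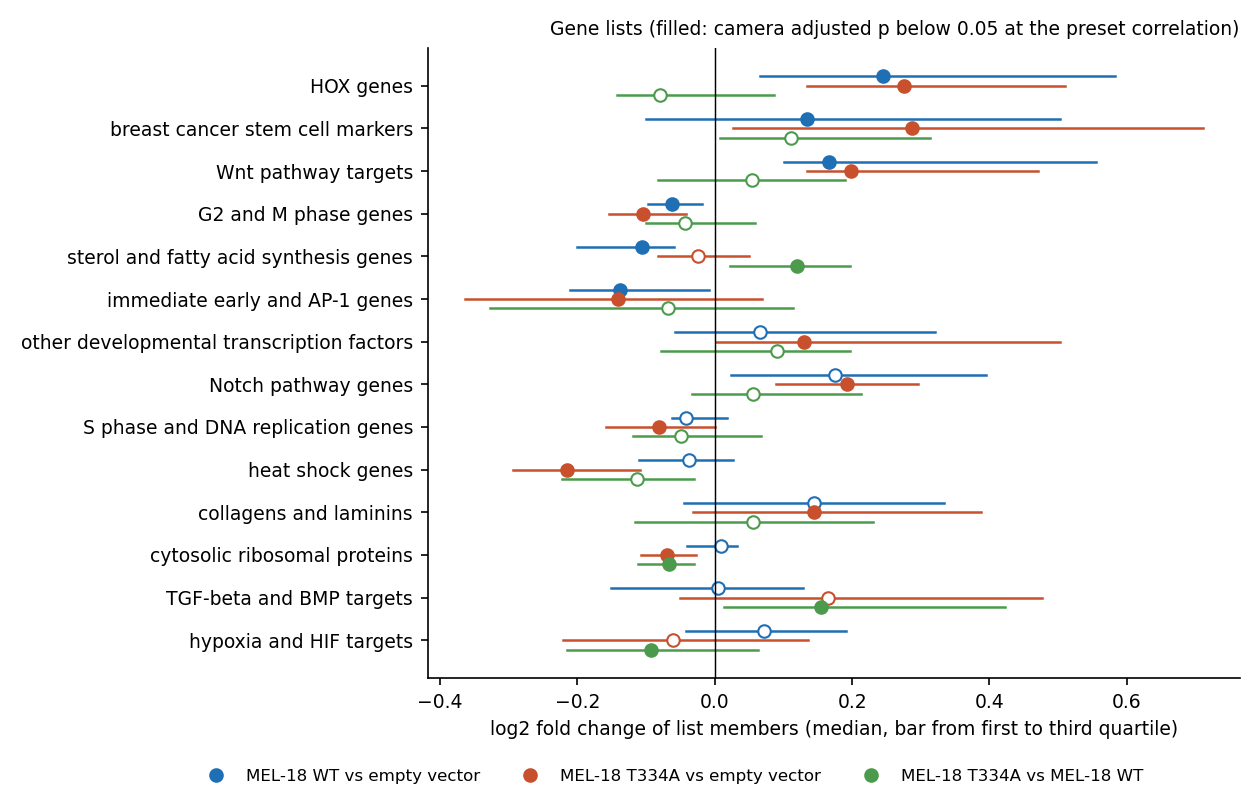
Median log2 fold change (horizontal axis) of the tested members of each gene list called in at least 1 comparison (vertical axis), with a bar from the first to the third quartile and a colour per comparison. Filled points were called by camera at the preset correlation of 0.01: 6, 11 and 4 lists. With an estimated correlation 0 lists were called.

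MEL-18 T334A against MEL-18 WT tested whether the mutant differed from the wild type. PDGFRA was called in opposite directions against the vector, at 18.5 ± 0.43 CPM in MEL-18 WT and 0.79 ± 0.24 CPM in MEL-18 T334A cells, against 4.36 ± 0.52 CPM with the vector (log2 fold change between the MEL-18 groups -4.55 ± 0.12). FABP4 went the other way, from 0.55 ± 0.16 to 8.90 ± 1.22 CPM (4.01 ± 0.16). LY9 held 6 counts in MEL-18 T334A cells against 1115 in MEL-18 WT cells (ratio 181, 95% interval 82.9 to 494), and TMPRSS15 stood at 1.55 ± 0.22 against 82.7 ± 1.84 CPM. RYR2, EPHA5, KCNN3 and GPM6A were higher in MEL-18 T334A cells by 5.20 ± 0.13, 4.40 ± 0.10, 2.97 ± 0.14 and 2.46 ± 0.11, and MAP2, a neuronal microtubule protein, by 1.52 ± 0.07. RFPL4A stood at 23.3 ± 1.06 against 8.22 ± 0.775 CPM and RFPL4AL1 at 8.99 ± 0.71 against 3.05 ± 0.46 CPM, with the caution that they are near-identical copies. MAGEB1, MYH13, CPPED1, RASGRP3 and PPP2R2C were lower by -4.81 ± 0.22, -3.13 ± 0.20, -3.11 ± 0.11, -2.85 ± 0.10 and -2.41 ± 0.15. GDF15, a stress-induced cytokine, was lower at -1.87 ± 0.12, with 3.11 ± 0.79 against 11.4 ± 1.53 CPM. The neighbours of LY9, TMPRSS15, RASGRP3, KCNN3 and GPM6A had medians of 0.14, -0.14, -0.15, 0.14 and -0.13.

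Between the MEL-18 groups 6034 genes were called, 3090 higher and 2944 lower in MEL-18 T334A, with a median change of 1.15-fold; 247 changed more than 2-fold, 106 higher and 141 lower, and 187 passed the test against 1.5-fold. With library totals alone 58.4% of calls were higher, against 51.2% with TMM. Replicates did not overlap in 48.7% of tested genes. TGF-beta and BMP targets rose in 13 of 23 cases and fell in 2, the same adjusted over the list alone (adjusted p = 0.00258, and adjusted p = 0.734 with an estimated correlation). The activin subunit INHBA was higher by 1.05 ± 0.18, beside neighbours at 0.18, the transcriptional regulator ID4 by 0.98 ± 0.05, beside neighbours at 0.10, PMEPA1 by 0.90 ± 0.07 and the matrix protein TGFBI by 0.76 ± 0.04, the last from 35.6 ± 1.43 to 60.2 ± 3.70 CPM. Sterol and fatty acid synthesis genes were higher in 19 of 32 cases and lower in 2 (19 and 3 adjusted over the list alone; adjusted p = 6.18e-04, and adjusted p = 0.734 with an estimated correlation). FDFT1 was higher by 0.51 ± 0.03, beside chromosome 8 neighbours at 0.34, and CYP51A1 by 0.31 ± 0.03, beside chromosome 7 neighbours at 0.16. Medians, means and tests differed in sign for collagens and laminins here (median 0.06, mean -0.08, test higher but not called, adjusted p = 0.392). Hypoxia targets were lower in 16 of 34 cases and higher in 6 (17 and 6 adjusted over the list alone; adjusted p = 0.0168, and adjusted p = 0.734 with an estimated correlation). The carbonic anhydrase CA9 stood at 2.99 ± 0.56 against 8.41 ± 0.21 CPM, and DDIT4, ADM and hexokinase HK2 were lower at -0.88 ± 0.09, -0.73 ± 0.05 and -0.68 ± 0.04. Neighbours of CA9 stood at -0.13 and those of DDIT4 at 0.23. Ribosomal protein genes were lower in 21 of 52 cases and higher in 5 (22 and 5 adjusted over the list alone; adjusted p = 0.0188, adjusted p = 0.854 with an estimated correlation, adjusted p = 0.0870 without MEL-18 WT replicate 2 and adjusted p = 0.295 without MEL-18 T334A replicate 1). Without MEL-18 T334A replicate 3, 8 lists were called rather than 4, and 7 with the shift of the neighbours taken out. The metallothionein list was not called, but MT1A stood at 0.463 ± 0.186 against 3.74 ± 0.249 CPM, and in the interferon list RSAD2 was lower, with 18 counts against 77 (ratio 4.17, 95% interval 2.47 to 7.40), and MX1 higher at 0.83 ± 0.13, beside neighbours at -0.11.

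Both MEL-18 groups were compared with the same 3 vector libraries. With PCGF2 left out, 1455 genes were called higher and 1015 lower in both comparisons, against 498 and 476 for independent lists. Opposite calls were made for 357 genes, against 973 for independent lists; there were 237 with DESeq2, 157 with the neighbours' shift taken out, and 4 against a minimum change of 1.5-fold. Across genes, which are not independent replicates, 66.8% of log2 fold changes had the same sign in both comparisons, against 66.9% in 100 simulated datasets of unchanged groups. Their Pearson correlation was 0.516, against 0.516 simulated, their Spearman correlation 0.481, against a mean of 0.453 and a highest value of 0.470 simulated, and their covariance 0.0836 against 0.0115 simulated, a difference of 0.0721. The sign share and the Pearson correlation matched what shared vector libraries gave in unchanged groups. These measures are therefore no evidence for or against a shared response. The vector group cannot be split into parts of at least 2 libraries, so the part of the overlap that comes from the shared controls was not separated. The simulated datasets held no real differences between groups, and 0 genes were called in both comparisons in them. They therefore give no expected number of shared calls for groups that do differ. A trait of the vector cultures alone would move both comparisons the same way. The difference in covariance does not separate such a trait from a shared effect of MEL-18. Of the 4241 genes called in MEL-18 WT, 2470 (58.2%) were called in the same direction in MEL-18 T334A. For 1592 genes (37.5%), MEL-18 T334A differed from MEL-18 WT in the direction opposite to the change of MEL-18 WT from the vector, and 1021 of these were not called between MEL-18 T334A and the vector. For 783 genes, MEL-18 T334A differed from MEL-18 WT in the same direction as MEL-18 WT from the vector. Both of these contrasts use the same MEL-18 WT libraries, which by itself favours opposite calls, and the share expected from that was not computed.

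**Figure D3:**
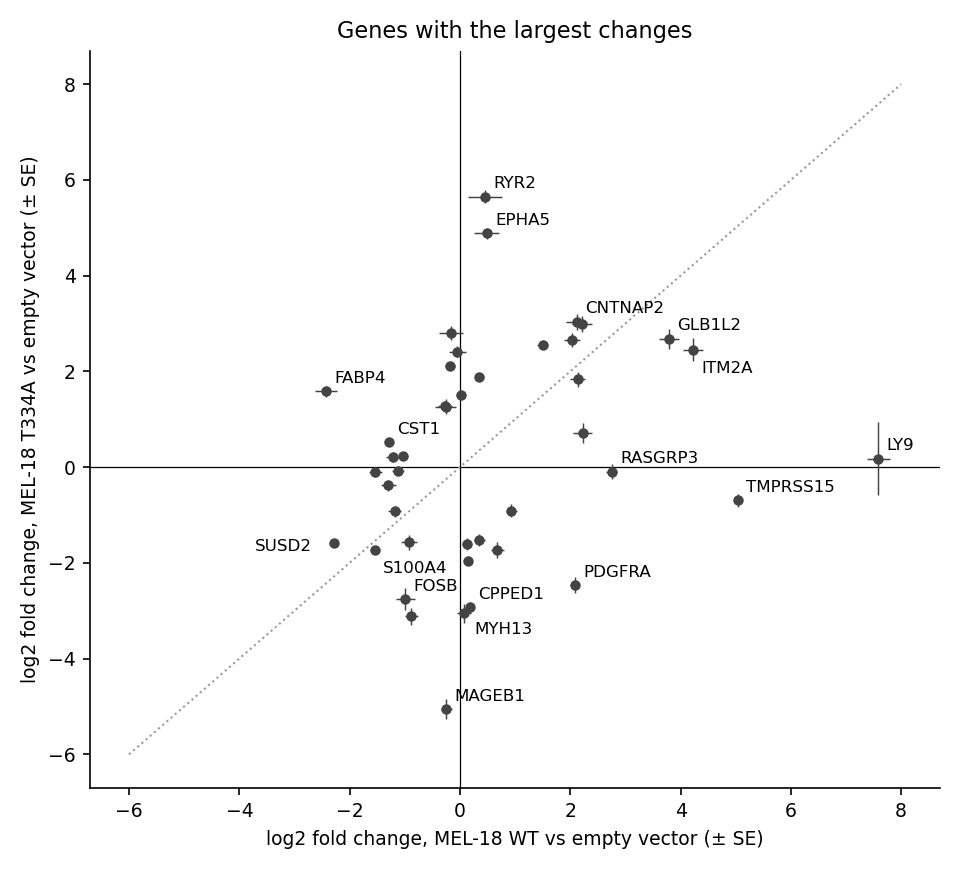
Log2 fold change against the vector in MEL-18 WT (horizontal axis) and MEL-18 T334A (vertical axis) for the genes with the largest changes in any comparison, PCGF2 left out, with SE bars and a dotted line of equal change. LY9 and TMPRSS15 lie far to the right, RYR2 and EPHA5 at the top, and PDGFRA and FABP4 in opposite quadrants.

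Neighbouring genes shifted together. In chromosomal order, adjacent genes had Spearman correlations of log2 fold changes of 0.227 for MEL-18 WT against the vector, 0.221 for MEL-18 T334A against the vector and 0.259 between the MEL-18 groups, where the highest of 1000 random orders of the genes gave 0.0265, 0.0241 and 0.0255. Of 349 blocks of 40 expressed genes, 1, 5 and 8 had at least 75% of genes called in the same direction, and 0 did in random orders. The block from PSMB4 to TPM3 on chromosome 1 was lower in MEL-18 WT, with a median of -0.20 and 77.5% of genes called lower. On chromosome 10, 82.5% of genes from GRK5 to PTPRE were higher in MEL-18 T334A than with the vector (median 0.32), and on chromosome 2, 80% from MDH1 to ADD2 were lower (median -0.31). Between the MEL-18 groups, 85% of genes from TNFRSF10D to GTF2E2 on chromosome 8 were higher (median 0.36), and 77.5% from WASH1 to SNAPC3 on chromosome 9 lower (median -0.33). With the shift of the neighbours taken out, an alternative chosen after the data were seen, 3136, 5693 and 4435 genes were called, of which 2565, 4729 and 3527 were also called without this step. Adjacent genes then still had Spearman correlations of 0.0655, 0.0701 and 0.0504, above the highest random orders. Values with the shift taken out are therefore not free of regional shifts.

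**Figure D4:**
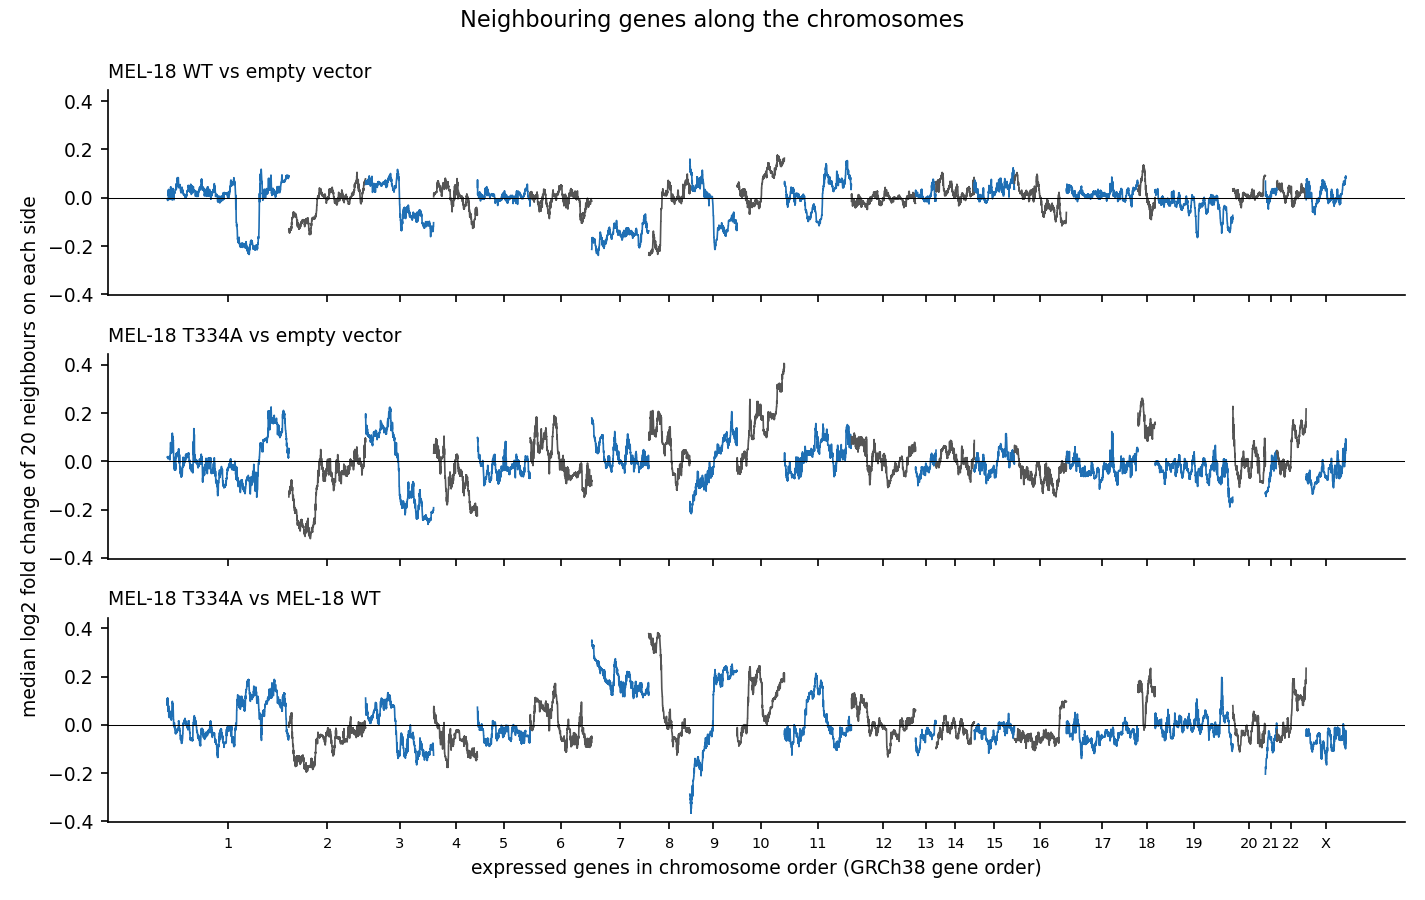
Median log2 fold change of the 20 expressed neighbours on each side of a gene (vertical axis) along the genes in chromosome order (horizontal axis, colours alternating by chromosome), for the 3 comparisons. Called blocks lie on chromosomes 1, 2, 7, 8, 9 and 10, with medians from -0.33 to 0.36.

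Markers of other cell types were read in the same libraries. Of 6 leukocyte markers, 5 were under 1 CPM in every library. CD68 stood at 54.3 ± 1.05, 54.6 ± 2.64 and 50.3 ± 2.67 CPM with the vector, MEL-18 WT and MEL-18 T334A, and was called lower in MEL-18 T334A than with the vector (log2 fold change -0.11 ± 0.04, edgeR adjusted p = 0.0330). Of 5 endothelial markers, in the same order of groups, KDR stood at 1.01 ± 0.108, 1.11 ± 0.135 and 1.68 ± 0.198 CPM, PECAM1 at 0.951 ± 0.181, 0.474 ± 0.117 and 0.330 ± 0.0440 CPM, CDH5 at 0.948 ± 0.219, 0.605 ± 0.0399 and 0.204 ± 0.0579 CPM, VWF at 0.287 ± 0.178, 0.246 ± 0.0865 and 0.273 ± 0.0911 CPM, and TEK at 0.152 ± 0.0763, 0.131 ± 0.0539 and 0.199 ± 0.150 CPM. Of the markers of the embryonic kidney line used for packaging viruses, CNTNAP2 reached 6.86 CPM and the other 5 stayed under 1 CPM. Among fibroblast markers, PDGFRA moved as given above, DCN and LUM had at most 1 and 3 counts in any library, and COL3A1 stayed under 1 CPM. PDGFRB stood at 6.32 ± 0.0892, 7.91 ± 0.494 and 9.54 ± 1.64 CPM with the vector, MEL-18 WT and MEL-18 T334A, and COL1A1 at 8.79 ± 0.653, 11.8 ± 0.721 and 12.7 ± 1.55 CPM; both were called higher than with the vector in both MEL-18 groups. Of 6 luminal markers, EPCAM stood at 7.47 ± 0.329, 10.1 ± 0.466 and 12.2 ± 0.363 CPM and GATA3 at 6.86 ± 0.582, 7.39 ± 0.285 and 7.46 ± 0.358 CPM, and the other 4 stayed under 1 CPM.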

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

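Genes that the rule took, with or without a value above, were singled out here when MEL-18 WT and MEL-18 T334A changed them in opposite directions against the vector and the difference between the MEL-18 groups was itself called by edgeR. This selection, the removal of the neighbours' shift and the tests on random gene order, the amount of MEL-18, the neighbours of single genes, the more and less expressed genes of a block, leukocytes and sequencing depth were chosen after the data were seen.

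The log2 fold change between MEL-18 T334A and MEL-18 WT was positive for FABP4 (4.01), CST1 (1.82), F13A1 (1.26), TIMP4 (0.99), COL13A1 (0.96), ADAM8 (0.64), CDH11 (0.57), FDFT1 (0.51), DUSP4 (0.50), LOXL2 (0.49), CCL2 (0.46), KRT7 (0.38), PHF19 (0.29) and TGFB2 (0.28). It was negative for TMPRSS15 (-5.73), PDGFRA (-4.55), MT1A (-2.997), PPP2R2C (-2.41), GDF15 (-1.87), SPNS2 (-1.84), CA9 (-1.49), ADM (-0.73) and F3 (-0.60). Neighbours were shifted the same way beside DUSP4 (0.36), FDFT1 (0.34), LOXL2 (0.33), ADAM8 (0.20), PHF19 (0.18), COL13A1 (0.17) and TGFB2 (0.14), and with that shift taken out these genes stood at 0.15, 0.17, 0.17, 0.41, 0.11, 0.79 and 0.16. Among the genes with a negative change, neighbours were shifted the same way beside TMPRSS15 (-0.14) and CA9 (-0.13), which then stood at -5.60 and -1.37. The neighbours of the other genes stood between -0.11 (CCL2) and 0.036 (FABP4).

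Genes that lie side by side shifted together. A random order of genes was excluded, with a permutation p of 0.001, the smallest that 1000 permutations can give, and so were GC content and transcript length, since the correlation of adjacent genes kept at least 0.927 of its size without them. Between the MEL-18 groups, with PCGF2 at 1286 and 1420 CPM, 8 blocks were called, against 5 between MEL-18 T334A and the vector. The 8 lay on chromosomes 7, 8 and 9, and the small difference in PCGF2 RNA argues against its amount as their cause. MEL-18 protein was not measured. The blocks called against the vector lay on chromosomes 1, 2 and 10. This separation by chromosome rests on the share of called genes asked of a block, and shifts of neighbours crossed it. In MEL-18 WT against the vector, the chromosome 8 neighbours of FDFT1 stood at -0.23 and those of FABP4 at 0.06. Between the MEL-18 groups, the chromosome 10 neighbours of ADAM8, COL13A1 and DDIT4 stood at 0.20, 0.17 and 0.23, and those of BMI1 at -0.0095. The blocks called against the vector were not among the 8, so the test cannot exclude the amount of MEL-18 as their cause. Gained or lost chromosome segments in the transduced lines are a candidate explanation. To test it, every other gene was used to pick blocks whose median lay beyond that of 1000 random orders, and the genes left out were compared. The 6 blocks picked were all from the comparison of the MEL-18 groups, several of them side by side on chromosome 8. Their more expressed genes moved by 0.342 ± 0.0125 (SE) and their less expressed genes by 0.311 ± 0.0269 in the direction of the block. The mean difference was 0.0313 ± 0.0215, where a change of dosage needs a small one. In single blocks it ran from -0.0187 to 0.113, and the SE treats blocks that lie side by side as independent. The test does not separate a change of dosage from other causes that move all genes of a stretch, and the shifts in the other comparisons were not covered. As construct and transduced line could not be told apart, a regional effect of MEL-18 on chromatin was not tested and stays open.

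LY9 and TMPRSS15 were high in the MEL-18 WT libraries alone, and RYR2 and EPHA5 in the MEL-18 T334A libraries alone. Their neighbours had medians from -0.21 (LY9) to 0.13 (RYR2), too small for these changes. With that shift taken out the smallest change was 4.96, an outcome that these sizes fixed in advance. Leukocytes were excluded as the source of LY9, since PTPRC stood at 0.309 CPM in MEL-18 WT libraries against 10.5 CPM for LY9. Whether these genes follow from MEL-18, from the site of the provirus or from the cells that founded the transduced cultures was not tested.

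MEL-18 T334A replicate 1 had counts for more genes than the other libraries. Thinned to the smallest library it still had 20321, against at most 19532 (SD 234), which excludes depth. Its share of reads from 493 genes taken as silent was 0.941 of the highest other library. These genes held 947 to 1229 reads in each library, so a large excess was absent but a small one would not show. Genomic DNA was therefore not excluded. No biological explanation was tested. Without it, 6060 genes were called against the vector and 5322 against MEL-18 WT.

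In fits of the compared groups alone, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes in each comparison. The real splits gave 4760, 6351 and 5823 genes and the highest others 0, 0 and 0, and 10 splits are too few for a share under 0.05. Each other split puts libraries of both groups on both sides, so differences between the groups enter its spread. Its low count was thus largely fixed in advance.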

How the results depend on the processing

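The removal of the neighbours' shift was chosen after the data were seen; the other alternatives were fixed before. Against a 1.5-fold minimum, 191, 378 and 187 genes were called for MEL-18 WT and MEL-18 T334A against the vector and between them, and the shared response fell to 90 and opposite calls to 4, since that test asks for larger changes. DESeq2 gave 3355, 5734 and 4953, with 237 opposite calls, and the other settings stayed within 1.5 times for genes called. Without single libraries the counts ran from 3441 to 3626, 5840 to 6878 and 4948 to 6304, the shared response from 2014 to 2602, opposite calls from 238 to 462 against 357, and called lists from 5 to 7, 7 to 14 and 3 to 8. The upper ends 6878, 6304, 2602, 462, 14 and 8 were those without MEL-18 T334A replicate 3, which differed most from its own group. With an estimated correlation 0, 0 and 0 lists were called by camera (smallest adjusted p = 0.127, 0.299 and 0.734), and what drove this loss was not tested. With the neighbours' shift taken out, 7 lists were called between the MEL-18 groups, and 157 genes had opposite calls. A term for the replicate number gave 3963, 6496 and 5757 genes, but numbers did not pair libraries: same-number correlations ran from -0.0791 to 0.0137, and 0 of 9 libraries were closest to their own number.

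For 401 results of named genes, 6272 values under alternatives kept direction and call, 501 lost the call and 17 changed sign. With the neighbours' shift taken out, MCM7 and RPS27 stood at 0.0127 and 0.0164 in MEL-18 WT against the vector; BUB3, MKI67, MSMO1, NDUFB4 and NDUFV2 at -0.0299, -0.119, 0.00240, 0.0251 and -0.0353 in MEL-18 T334A against the vector; and NOTCH1, DLC1, ANLN, RFC2 and RPS24 at -0.0633, -0.0893, -0.0606, -0.0132 and -0.0225 between the MEL-18 groups. Of these, MKI67 (edgeR adjusted p = 0.00326) and DLC1 (adjusted p = 0.0262) were then called in the opposite direction, with the error of the shift left out of both p-values. BMI1, not called there, stood at -0.00413 without a filter, -0.00201 with voom, -0.0225 thinned, and from -0.0718 to 0.0635 without single libraries. Apart from the step named, the cause was not tested. Depth limits genes with few counts, whose ratios have wide intervals.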

Other observations

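The genes here were chosen after their values were seen. NFYC-AS1, an antisense RNA at NFYC, stood at 38.1 ± 3.06 CPM with the vector, 1.92 ± 0.168 CPM with MEL-18 WT and 1.94 ± 0.27 CPM with MEL-18 T334A (log2 fold changes -4.31 ± 0.09 and -4.30 ± 0.09), while NFYC itself stood at 50.1 ± 0.797, 52.9 ± 1.42 and 46.1 ± 0.55 CPM. The strand setting of the counting is not stated, so reads of overlapping genes were not told apart. Against the same vector libraries, SYT7 rose in MEL-18 WT and MEL-18 T334A by 1.86 ± 0.16 and 2.09 ± 0.16, SRRM3 by 1.28 ± 0.10 and 1.84 ± 0.10, ELFN2 by 1.13 ± 0.07 and 1.46 ± 0.07, and CACNG7 by 1.40 ± 0.15 and 1.48 ± 0.14. SEPT3 stood at 2.33 ± 0.14, 6.61 ± 0.383 and 13.8 ± 0.576 CPM with the vector, MEL-18 WT and MEL-18 T334A.

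In MEL-18 T334A cells MYH13 fell against the vector by 3.06 ± 0.21, MYH8 by 2.91 ± 0.34, MYHAS by 3.43 ± 0.31, MYH4 by 1.81 ± 0.38, MYH1 by 2.66 ± 0.48 and MYH2 by 2.25 ± 0.61, while MYH3, of the same cluster of skeletal myosin genes, was not called (-0.16 ± 0.09, adjusted p = 0.142). No test of the cluster was run. MAGEB2, of the same family as MAGEB1, fell from 47.7 ± 1.24 to 22.7 ± 0.518 CPM. COL4A6 fell with COL4A5, with 12 counts against 62 over 3 libraries each (ratio 5.44, 95% interval 2.91 to 11.1).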
